A study of Mus musculus with 2 samples.

How the data were processed

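Gene expression was measured by droplet single-cell RNA-seq (10x Genomics, 3′ V3 chemistry) in CD45+ leukocytes sorted by flow cytometry from tissue labeled as colorectal tumor of male C57BL/6 mice. The labels' text on extraction also speaks of normal colon, and the libraries were taken as tumor tissue from their titles. The tumors were raised with azoxymethane (AOM, 12 mg/kg), a colon carcinogen, and 3 cycles of 2.5% dextran sodium sulfate (DSS), which injures the colon epithelium. Per the labels, DSS was given for 7 days of each cycle and plain water for the next 14, and mice were fed ad libitum or given a fasting-mimicking diet (FMD) from cycle 2. Each diet had 1 library made from 4 pooled mice. Cells came from digested tissue and a Percoll gradient before the sort.

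Per the submitters' processing notes, CASAVA 1.8, Cell Ranger 3.1.0 and Seurat 2.3.4 were used with the mouse assembly GRCm38, with no role given for each tool. Per the file headers, the matrices were written by Cell Ranger 3.1.0. The deposited matrices hold counts, that is raw UMI counts per gene and cell barcode with no normalization, for 30905 genes. The other deposited lists name the barcodes and the genes of the matrix. The barcodes had already been selected, since the lowest total per barcode was 500 UMIs in both libraries. Whether Cell Ranger or the authors made that selection cannot be told from the counts. The ad libitum library held 6089 barcodes with 35712762 UMIs, and the FMD library held 5877 barcodes with 35280790 UMIs. Cluster names of the authors were not used here, so all cell classes were rebuilt from the counts. A symbol was on more than 1 line of the gene list for 65 symbols, and the first line was then used.

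Cells were kept with at least 200 detected genes and at most 20% of UMIs from mitochondrial genes. Scrublet, run per library in scanpy 1.11.5 with an expected doublet rate of 0.05, called 0.04% of ad libitum and 0.17% of FMD cells. Because those rates were so low, cells were also removed as doublets when they held at least 5 UMIs and at least 0.5 per 1000 UMIs of 2 of the B, T and myeloid marker panels, a filter added after the Scrublet result was seen. Removed barcodes had too few genes (475 ad libitum, 441 FMD), too high a mitochondrial share (661 and 694) or a doublet call (84 and 120). The kept cells were 4869 and 4622.

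Counts were scaled per cell and log-transformed. Both libraries were clustered together without batch correction, by Leiden (leidenalg 0.10.2) at resolution 1 on a shared-neighbor graph of 15 neighbors, from 30 principal components of 2000 variable genes with seed 1. Immunoglobulin genes, T cell receptor variable and joining segments, and mitochondrial and ribosomal protein genes were left out of the variable genes. The 25 clusters were named from marker lists by the fold of each marker over the mean of the other clusters, T cell subclasses by Trdc, Cd3e, Foxp3, Cd8a and Cd4, which gave 11 named classes. A cluster stayed unnamed when its median UMI count in at least 1 library lay far below that library's or when its leading genes held more markers of another class. The naming rule went through 3 versions after clusters and cell counts per library had been seen, and the first of them was run as an alternative.

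Heavy chain isotypes were called in cells thinned to 1000 UMIs. A cell was assigned the constant gene that held a share above 0.5 of at least 3 heavy chain constant UMIs, and shallower cells were left out. The same call in T cell classes was taken as the background from free RNA, which droplets take up from broken cells. It is not a like background for B cells, whose own Ighm counts against an Igha call. For gene levels, UMIs of a class were summed per library and divided by its UMIs outside immunoglobulin and mitochondrial genes. Counts of genes at least 2-fold apart and named genes were given for classes with at least 100 cells in each library and genes with at least 100 UMIs over both. Named genes were the 6 highest and 6 lowest log2 ratios (FMD over ad libitum) in B-like and helper T-like cells and the 4 highest and 4 lowest in the other classes, leaving out immunoglobulin variable, diversity and joining segments, mitochondrial, ribosomal protein and X-inactivation or Y-linked genes and gene models without a symbol. Heavy chain constant genes, Jchain and members of the gene lists were named in addition. The regulatory and CD8 T-like classes were thus given 4 and 4, although the rule allowed 6 and 6 for T cells taken as 1 class. A pooled T cell class was computed at first and dropped, and its interferon value was computed again after the results by class were seen. For 32 gene lists, the median log2 ratio of the members with at least 20 UMIs was taken where at least 5 members passed, with its percentile among 10000 random lists of the same size matched on mean expression in 20 bins. Of 285 list and class pairs computed, 61 were picked to be read, lists in classes whose cells can express them and the free RNA list in B-like cells. Not every such pair was picked, and a few others are printed beside them. Those not picked include proliferation in plasma-like cells (0.99 [0.68, 1.28]) and MHC class I presentation in macrophage or dendritic-like cells (−0.56 [−0.67, −0.47]). Which pairs to read was settled after the medians had been computed. Lists, thresholds, named gene rule and most alternatives were fixed before the data were examined.

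Shares have exact Clopper-Pearson intervals at the 95% level, ratios of shares have log-ratio (Katz) intervals, gene ratios have exact intervals for the ratio of Poisson counts, and list medians have intervals from 1000 Poisson draws of both sums. A count of 0 was set to a floor of 3 for a ratio. All of these cover counting error only. Intervals of gene ratios and list medians take each UMI as an independent count. They leave out the sampling of cells, so they are too narrow where a few cells hold many UMIs of a gene. With 1 library per group there is no replicate check, no p-value is given, and every comparison is between these libraries and not between the diets. On simulated pairs of libraries, the gene intervals covered 94.9% of unchanged genes in a large class and 95.7% in a small class, and 48 of 50 list intervals covered the simulated value. The simulated sums were drawn from the Poisson model that the intervals assume, without cells. They therefore check the calculation and not whether that model holds for these data.

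Alternatives, each changing 1 choice, were a mitochondrial limit of 10%, a minimum of 500 genes, no doublet removal, Leiden resolutions of 0.5 and 2, receptor and ribosomal genes kept for clustering, classes from marker scores per cell, other denominators, thinning to 500 or 2000 UMIs or none, isotype minimums of 1 and 10 UMIs, scaling by all UMIs or by TMM factors (trims of 30% and 5%), cells thinned before summing, gene minimums of 50 and 400 UMIs with list minimums of 10 and 50, and genes left out whose level in a class was under 0.1 of that in the class with most. After the data were seen, 8 more were added. These removed cells with a Scrublet score above 0.2, counted the unnamed cluster with B cell markers as B-like, lowered the class minimum to 30 cells, left out the cell with the most UMIs of each gene, left out the interferon-led B-like cluster, took each regulatory T-like cluster alone, used the first naming rule, or used another marker score. The planned marker score put only 41.6% of named cells in the broad class of their cluster and the added one 98.3%. Gene coordinates are from GENCODE M21 on GRCm38. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and matplotlib 3.10.9.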

Results

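Leukocytes from tissue labeled as colorectal tumor of mice fed ad libitum and of mice on a fasting-mimicking diet (FMD, a low-calorie diet that imitates fasting) were profiled as 1 library each, pooled from 4 mice. The kept cells were 4869 in the ad libitum library, with 33320620 UMIs and a median of 5508 UMIs and 1762 genes per cell, and 4622 in the FMD library, with 32030369 UMIs and medians of 5742.5 UMIs and 1826 genes. There was no replicate of either diet, so a difference below is between these libraries, ratios are log2 of FMD over ad libitum, and brackets hold 95% counting intervals.

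The first comparison asked which leukocytes differed in number between the libraries. Plasma-like cells, the antibody-secreting end stage of B cells, made up 1.91% [1.54, 2.33] of cells in the ad libitum library (93 cells) and 0.69% [0.47, 0.98] in the FMD library (32 cells), 2.76-fold lower, a log2 ratio of −1.46 [−2.04, −0.89]. Innate lymphoid-like cells, tissue lymphocytes without an antigen receptor, were 3.18-fold higher in the FMD library, at 0.88% against 2.81% (43 and 130 cells; 1.67 [1.18, 2.17]). Macrophage or dendritic-like cells were 1.85-fold higher, at 1.62% against 3.01% (0.89 [0.50, 1.28]). Regulatory T-like cells, which restrain other T cells, held 4.25% and 6.27% of cells (0.56 [0.31, 0.81]). Of that class, the cluster led by Il10 held 1.62% and 4.02% of kept cells (2.48-fold [1.91, 3.22]). Its cluster led by Penk held 2.63% and 2.25% (0.86-fold [0.66, 1.11]). The size of the innate lymphoid-like, macrophage or dendritic-like and regulatory T-like ratios depended on how cells were named. With classes from the planned marker score per cell they were 0.44, 0.08 and 0.07, and with the added marker score 1.19, 0.45 and 0.14. At Leiden resolution 0.5 the macrophage or dendritic-like class held 130 and 174 cells, against 79 and 139 in the main setting.

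B-like cells were the most numerous class in both libraries and differed little, with 2836 cells (58.25% [56.85, 59.64]) against 2586 (55.95% [54.5, 57.39]), a ratio of −0.06 [−0.11, −0.01]. Germinal center B-like cells, the dividing B cells of follicles, were 59 and 80 cells (0.51 [0.03, 1.00]); 11 and 8 of them had a UMI of the T cell gene Cd3e. All T, natural killer and innate lymphoid classes together made up 26.54% and 29.71% (0.16 [0.07, 0.26]), with helper or naive T-like cells at 12.47% and 13.41% (0.11 [−0.04, 0.26]) and gamma delta T-like cells at 1.46% and 1.04% (−0.49 [−1.01, 0.04]). CD8 T-like cells were 7.48% and 6.17% (−0.28 [−0.49, −0.06]), a ratio that was 0.03 at Leiden resolution 0.5. Of the 3 clusters in that class, the one led by Klra7 and Xcl1 and rich in natural killer receptor genes held 2.88% and 2.03% (−0.50) and had Cd8a in only 32.5% of its cells, although Cd3e in 85.5%, so its cells are not mainly CD8 T cells by this marker. The cluster led by Dapl1 and Cd8b1 (Cd8a in 76.9%) held 2.4% and 2.42%, and the one led by Ccl5 and Cd8a (92.5%) 2.2% and 1.71%. All myeloid classes together made up 3.25% and 4.54% (0.49 [0.19, 0.78]; 0.06 with classes from marker scores per cell), neutrophil-like cells 1.46% and 1.19% (−0.29 [−0.80, 0.21]). Mast-like cells were 8 and 16. A cluster led by Bhlhe41, Apoe, Ccr6 and Cd86 had B cell markers but kept no class name, and held 238 and 181 cells (−0.32 [−0.59, −0.05]). Other unnamed cells, in clusters of low depth in at least 1 library, were 3.96% and 3.46%. In 1 of these clusters dendritic markers scored highest, and its median was 1206 UMIs in the ad libitum and 3959 in the FMD library. It held 51 and 35 cells (0.72-fold [0.47, 1.11]), the other direction from the macrophage or dendritic-like class.

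**Figure D1:**
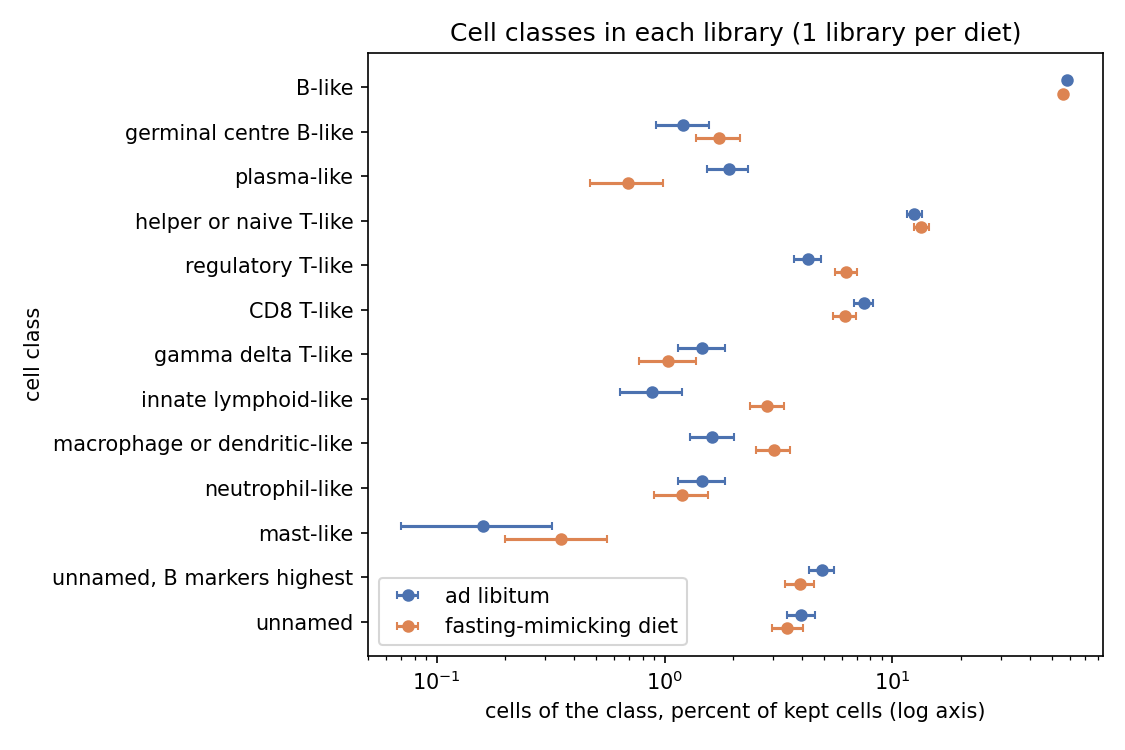
Cells of each class as a percent of the kept cells on a log axis, in the ad libitum and the FMD library, with exact 95% counting intervals as bars. Plasma-like cells lie lower in the FMD library (0.69% against 1.91%), and innate lymphoid-like (2.81% against 0.88%) and macrophage or dendritic-like cells (3.01% against 1.62%) lie higher.

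The next comparison was of IgA-positive cells, which the study's title names. IgA is the antibody class secreted onto mucosal surfaces, and its heavy chain constant region is encoded by Igha (ENSMUSG00000095079; GRCm38 chromosome 12, 113254830 to 113260236, minus strand). Among B-like, germinal center B-like and plasma-like cells at equal depth, 106 of 2980 were IgA cells in the ad libitum library (3.56% [2.92, 4.29]) and 24 of 2693 in the FMD library (0.89% [0.57, 1.32]), 3.99-fold lower, a log2 ratio of −2.0 [−2.63, −1.36]. The ad libitum calls were 84 plasma-like, 18 B-like and 4 germinal center B-like cells, and the FMD calls 23, 0 and 1. The B-like calls may be free RNA (below), so this ratio may take in some background. Without thinning the shares were 4.32% and 1.07%. Within the plasma-like class, 84 of 92 cells (91.3% [83.58, 96.17]) and 23 of 32 cells (71.88% [53.25, 86.25]) were IgA cells, a ratio of −0.35 [−0.67, −0.02]. The other FMD plasma-like cells were called as Ighm (2), Ighg2b (2), Ighg2c (2) and Ighg3 (3), and the other ad libitum ones as Ighg1 (2), Ighg2b (3) and Ighg2c (3).

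Igha was also lower as a sum over all kept cells, with 568115 UMIs (19181.2 CPM, scaled to the UMIs outside immunoglobulin and mitochondrial genes) against 210808 (7142.4 CPM), 2.69-fold and −1.43 on the log2 scale. Plasma-like cells held 98.8% and 97.1% of these UMIs. Per plasma-like cell, Igha was not lower in the FMD library by its mean (6036.25 and 6394.47 UMIs), although its median was (5445 and 4462). In B-like cells 18 of 2829 (0.64%) and 0 of 2581 cells were called IgA, where a count of 0 allows a share of up to 0.14%, and the ratio with the floor of 3 cells (0.116%) was −2.45. T cell classes, which make no antibody, gave 13 of 1247 (1.04%) and 2 of 1239 (0.16%) at the same depth. T cells make no Ighm, so free Igha passes the call more easily in them than in B-like cells. Without thinning, 20.98% and 3.22% of T-like cells were called IgA, against 1.23% and 0.15% of B-like cells. The T cell share is therefore not a like background, and it cannot settle whether the B-like calls were free RNA. Igha UMIs were in 60.8% and 26.1% of B-like cells (median depth 4967 and 5110.5 UMIs) and in 71.7% and 36.8% of helper or naive T-like cells (7061 and 7131 UMIs). In germinal center B-like cells 4 of 59 and 1 of 80 were IgA cells. In the unnamed cluster with B cell markers, 12 of 238 (5.04% [2.63, 8.64]) and 7 of 181 (3.87% [1.57, 7.81]) were IgA cells, above the T cell share at this depth. The libraries did not differ detectably there (−0.38 [−1.70, 0.93]). Without thinning, 15.13% and 10.5% of that cluster were IgA cells, below the T cell share in the ad libitum library (20.98%) and above it in the FMD library (3.22%).

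Within plasma-like cells the secretory genes had a median of −0.07 [−0.14, −0.01] over 18 members, which was −0.35 [−0.66, −0.17] with cells thinned to 1000 UMIs before summing, with Jchain (the joining chain of secreted IgA and IgM) at 0.01 [−0.01, 0.02] and Xbp1 (a regulator of secretion) at −0.27 [−0.35, −0.19]. The unfolded protein and integrated stress response list had a median of 0.16 [0.03, 0.27] over 16 members, of which 4 had an interval above 0 and none below, with Herpud1 at 0.38 and Atf4 at 0.26. The stress response median was −0.31 with the same thinning and 0.00 without the cell holding the most UMIs of each gene.

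The comparison of B-like cells asked what else differed in the most numerous cells. The peptide transporter gene Slc15a2 (ENSMUSG00000022899; chromosome 16, 36750177 to 36784962, minus strand) was 4.61-fold lower in the FMD library, with 1068 against 217 UMIs and a log2 ratio of −2.21 [−2.42, −1.99], and had a UMI in 7.49% and 1.67% of cells thinned to equal depth. Genes induced by type I interferon were higher in the FMD library, with a median of 0.53 [0.37, 0.68] over 21 members and percentile 100 among random lists. Immediate early and heat shock genes, which respond within minutes to stimulation or handling, were lower, with a median of −0.36 [−0.39, −0.32] over 22 members and percentile 0. Of 8538 genes with enough UMIs, 7 were at least 2-fold higher and 7 at least 2-fold lower.

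The highest ratios were those of 4 hemoglobin genes, Hba-a2 (8.38), Hba-a1 (7.20), Hbb-bs (6.81) and Hbb-bt (3.44), whose FMD UMIs lay in 2 to 8 cells each. Then came the interferon-induced antiviral genes Mx1 (1.38 [0.79, 2.00]) and Ifit3 (1.32 [0.80, 1.86]). Their levels per cell were 0.064 and 0.079 of those in macrophage or dendritic-like cells, under the 0.1 below which this level by itself leaves free RNA open. Macrophage markers, taken up below, argue against macrophage RNA as the source for the interferon list as a whole. Of the 21 interferon members, 14 had an interval above 0 and none below, among them Irf7 (0.51 [0.31, 0.72]), Bst2 (0.59 [0.43, 0.75]) and Rtp4 (1.00 [0.62, 1.38]), while Isg15 was at −0.13 [−0.39, 0.13]. At equal depth, 4.21% [3.50, 5.01] and 7.01% [6.06, 8.07] of B-like cells had at least 3 UMIs of the list. The median was 0.17 without genes at the free RNA level and 0.01 without the B-like cluster led by interferon genes.

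At the low end, Jchain (−2.33 [−2.62, −2.05]), Igha (−1.75 [−1.87, −1.64]) and Ighg2b (−1.10 [−1.48, −0.73]) are plasma cell transcripts and S100a9 (−1.76 [−2.32, −1.23]) is a neutrophil transcript, each at a level per cell that rounds to 0.0 of that in the cells making it, so at the level of free RNA. Cdk5rap1, a tRNA-modifying enzyme, was at −1.09 [−1.64, −0.57]. Of the immediate early and heat shock members, 20 had an interval below 0 and none above. The chaperone genes Hspa1a and Dnajb1 were at −0.78 and −0.72, and the transcription factor genes Egr1, Jun and Fos at −0.62, −0.37 and −0.36. Of the B-like clusters, the one led by heat shock genes held 3.61% of kept cells in the ad libitum and 2.1% in the FMD library, and the one led by Egr3 and Myc 17.91% and 14.21%. Immediate early and heat shock genes also mark handling of the cells. Together they took 1.21% of all kept UMIs in the ad libitum and 1.1% in the FMD library. Their median was also below 0 in plasma-like (−0.42), macrophage or dendritic-like (−0.29), regulatory T-like (−0.20), germinal center B-like (−0.19) and neutrophil-like cells (−0.14). It was near 0 in helper or naive (−0.03), CD8 (−0.01) and gamma delta T-like (0.00) and innate lymphoid-like cells (0.02). NF-kB and B cell activation genes were lower in B-like cells, with a median of −0.13 [−0.17, −0.09] and 11 of 18 members below 0 by their interval, such as Egr3 (−0.33), Myc (−0.31) and Cd69 (−0.19), while Cd86 was higher (0.22). Genes induced by glucocorticoids, the adrenal stress hormones, were lower as well (−0.16 [−0.22, −0.12]; 10 of 13 below), with Sgk1 at −0.75 and Tsc22d3 at −0.17, and Dusp1 (−0.38) is on both this list and the immediate early one.

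Fatty acid and sterol synthesis genes were slightly higher (0.11 [0.06, 0.18]; 6 of 19 members above and none below), with Elovl5 at 0.31 and Idi1 at 0.26. Fatty acid oxidation genes, which fasting induces in many tissues, had a median of −0.07 [−0.15, 0.01] with 21 of 22 members across 0. Medians were 0.05 [0.00, 0.11] for glycolysis, 0.05 [0.02, 0.08] for the nuclear-encoded respiratory chain, −0.02 [−0.08, 0.03] for FOXO and nutrient restriction and 0.03 [−0.03, 0.09] for the unfolded protein and integrated stress response. Genes of IgA switching and homing were at 0.08 [0.00, 0.15] over 18 members, with the TGF-β signaling genes Smad3 (0.31) and Tgfbr2 (0.14) and the homing integrin Itga4 (0.25) higher and the BAFF receptor gene Tnfrsf13c lower (−0.16). Switch recombination machinery was at −0.09 [−0.19, 0.01], with 15 of 17 members across 0, Msh6 at −0.63 and Apex1 at 0.20. Secretory and plasma genes were at 0.08 [0.02, 0.14], with Sel1l at 0.47 and Pdia6 at 0.19. Medians lay near 0 for heavy chain constant genes (−0.02 [−0.17, 0.03]), naive and resting B (0.02 [−0.02, 0.05]), germinal center B (−0.05 [−0.19, 0.10]), MHC class II presentation (0.01 [−0.02, 0.04]), MHC class I presentation (−0.05 [−0.09, −0.01]), proliferation (−0.02 [−0.14, 0.10]) and ribosomal proteins (−0.01 [−0.02, −0.01]; 16 of 80 members above and 40 below). The fibroblast, endothelial and erythroid list had 5 members with enough UMIs and a median of 6.81 [6.25, 7.47] that came from the 4 hemoglobin genes, with the endothelial gene Pecam1 at 0.09. Of the epithelial list too few members passed for a median, and its gene Epcam had 60 and 86 UMIs (0.61 [0.12, 1.11]).

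**Figure D2:**
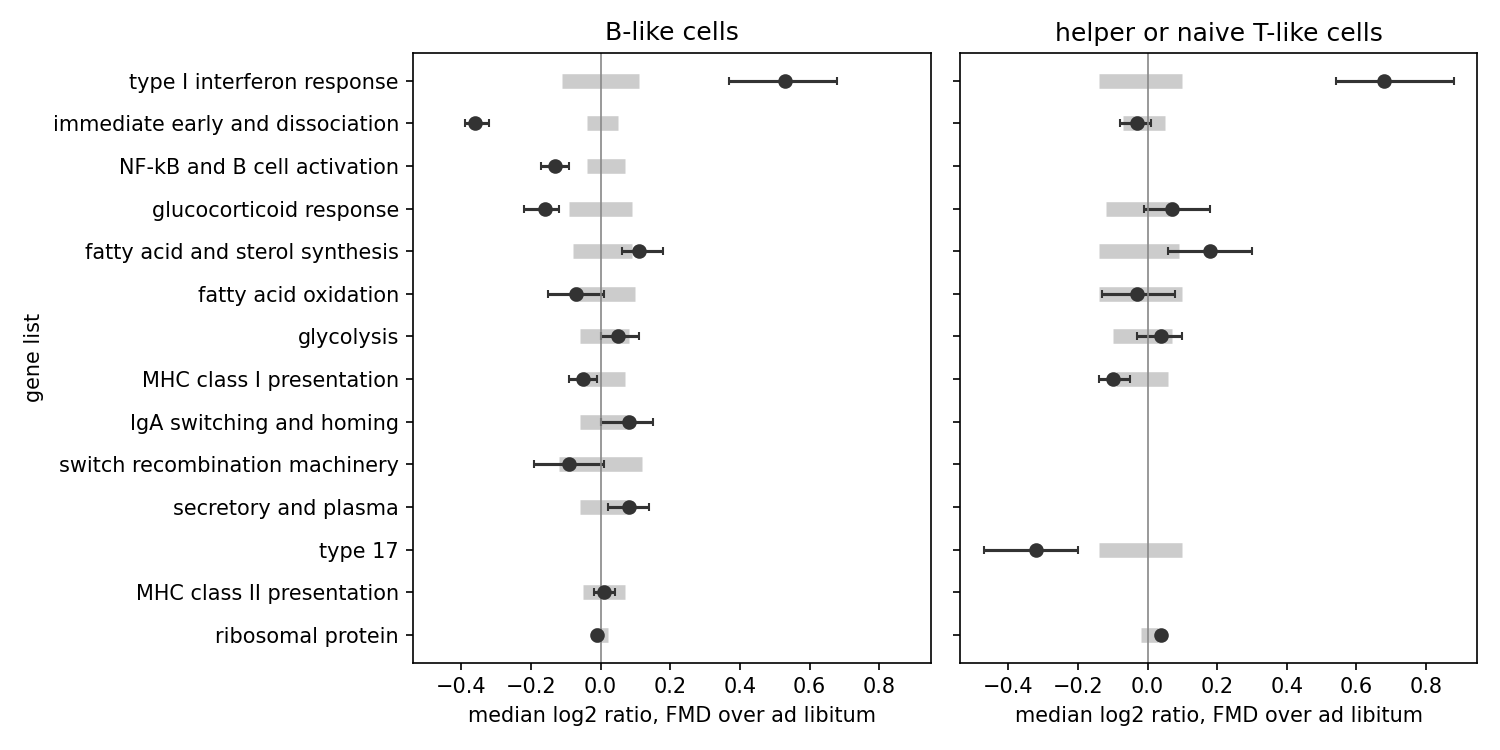
Median log2 ratio (FMD over ad libitum) of gene lists in B-like and in helper or naive T-like cells, with 95% counting intervals as bars and the central range of matched random lists in gray; a list is drawn only in a class whose values are reported. Interferon genes lie at 0.53 and 0.68, and type 17 genes in helper or naive T-like cells at −0.32.

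**Figure D3:**
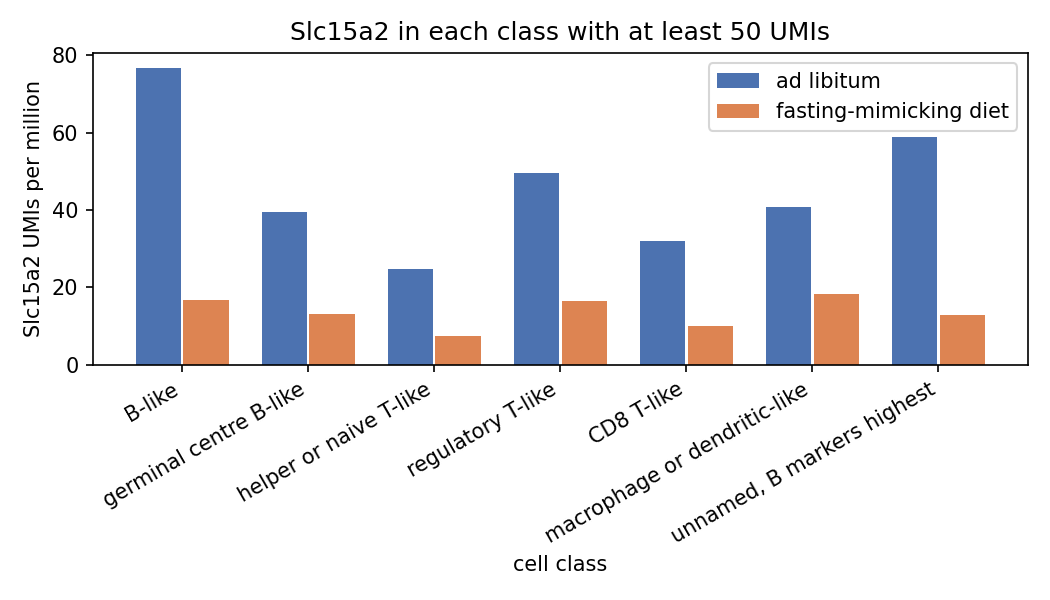
Slc15a2 level in CPM in the ad libitum and the FMD library, in each class with at least 50 UMIs of the gene. Bars are 76.8 and 16.7 in B-like cells, and the FMD bar is the lower one in all 7 classes.

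Helper or naive T-like cells were compared for the cytokines that shape mucosal immunity. Il17a (ENSMUSG00000025929; chromosome 1, 20730905 to 20734496) and Il17f (ENSMUSG00000041872; chromosome 1, 20777146 to 20790617), which encode cytokines that drive neutrophil and epithelial responses, were 6.12-fold and 5.88-fold lower in the FMD library. Il17a had 972 UMIs in 67 cells against 166 in 31 cells (−2.61 [−2.86, −2.37]), and Il17f had 445 against 79 UMIs (−2.56 [−2.92, −2.21]). Their levels per cell were 0.046 and 0.348 of those in gamma delta T-like cells. At equal depth a UMI of either gene was found in 8.1% [6.05, 10.57] and 2.59% [1.49, 4.17] of these cells, against 0.07% of ad libitum B-like cells and 0 of 2581 FMD ones, which allows up to 0.14%. Interferon genes were higher in the FMD library, with a median of 0.68 [0.54, 0.88] and 16 of 20 members above 0 by their interval.

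Of 6801 genes, 13 were at least 2-fold higher and 29 at least 2-fold lower. Among the highest were Ifit3 (3.04 [2.17, 4.04]), Mx1 (1.56 [0.89, 2.27]), Slfn5 (1.5 [1.07, 1.94]) and Ifit1 (1.48 [0.97, 2.01]), all induced by interferon, the gamma delta receptor gene Trdc (2.46 [1.79, 3.21], in 29 FMD cells, at 0.004 of the level in gamma delta T-like cells) and Sostdc1 (6.69 [4.18, 12.01], 1 UMI against 108 in 9 cells). Several of these were lower under other settings: Ifit3 was at 1.3 and Ifit1 at 0.03 at Leiden resolution 0.5, Slfn5 at 0.92 with at most 10% mitochondrial UMIs, Trdc at 0.91 with receptor and ribosomal genes kept for clustering, and Sostdc1 at 1.85 and Mx1 at 0.24 with cells thinned to 1000 UMIs before summing. Other interferon members were Irf7 (1.23) and Isg15 (0.63). The lowest were the lambda light chain gene Iglc1 (−3.99 [−4.97, −3.15], free RNA of plasma cells), Ermn (−2.89 [−3.69, −2.18]), the type 17 cytokines, the chemokine gene Ccl20 (−2.51 [−2.86, −2.18]; −4.05 without its top cells) and Ppp1r14c (−2.08 [−2.79, −1.42], at 0.078 of the level in gamma delta T-like cells). The type 17 list had a median of −0.32 [−0.47, −0.20], with 7 of 14 members below 0, Il22 at −1.31 (504 and 212 UMIs) and Rora at −0.27. In gamma delta T-like cells (71 and 48 cells) the same list was not lower. Its median there was 0.11 [−0.07, 0.26], with 4 of 13 members above 0 by their interval and 2 below. The interferon result shifted with how T cells were divided: it was 0.03 at Leiden resolution 0.5, where Mx1 was −0.20, and 0.91 without doublet removal. Helper and CD8 T-like cells pooled had a median of 0.57 [0.44, 0.75], and between 0.55 and 0.67 under 7 other settings.

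Among the other lists in helper or naive T-like cells, fatty acid and sterol synthesis was higher (0.18 [0.06, 0.30]), with Scd1 at 0.47 and Elovl6 at −0.77. Cytotoxic effector genes were lower (−0.24 [−0.41, −0.05]; 6 of 15 members below and 1 above), as were regulatory T genes (−0.18 [−0.31, −0.06]) and MHC class I presentation (−0.10 [−0.14, −0.05]). Follicular helper T genes were at −0.12 [−0.28, −0.02], within the central range of matched random lists (percentile 5.4) and at 0.02 at Leiden resolution 0.5, with 7 of 11 members across 0, Il21 at −1.34 and Il4 at −2.13 (21 and 5 UMIs). The respiratory chain was at −0.06 [−0.09, −0.02] and ribosomal proteins at 0.04 [0.03, 0.04]. Intervals reached 0 for fatty acid oxidation (−0.03 [−0.13, 0.08]), glycolysis (0.04 [−0.03, 0.10]), FOXO and nutrient restriction (−0.06 [−0.12, 0.00]), glucocorticoid response (0.07 [−0.01, 0.18]), unfolded protein and integrated stress response (0.04 [−0.07, 0.16]), immediate early and dissociation (−0.03 [−0.08, 0.01]), checkpoint and exhaustion (−0.01 [−0.22, 0.21]), naive and central memory T (0.04 [−0.05, 0.15]) and proliferation (0.15 [0.00, 0.31]).

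Regulatory T-like cells were compared for their suppressive program. In the FMD library, Gzmb (granzyme B) was 2.97-fold higher (1.57 [1.40, 1.75]; 322 against 1395 UMIs, at 0.051 of the level in mast-like cells), the inhibitory receptor gene Lag3 3.1-fold higher (1.63 [1.30, 1.98]) and the suppressive cytokine gene Il10 higher (0.96 [0.78, 1.14]). The lineage factor gene Foxp3 was level (0.09 [−0.05, 0.22]), while Ikzf4 (−1.26), Ikzf2 (−0.72) and most other members of the regulatory T list were lower (−0.36 [−0.44, −0.29]; 10 of 15 below and 3 above). The class had a pair of clusters. Most ad libitum cells were in the one led by Penk, a neuropeptide precursor gene, and most FMD cells in the one led by Il10.

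Of 4713 genes, 19 were at least 2-fold higher and 14 lower. Nkg7 (2.51 [1.76, 3.36], 24 FMD cells, at 0.053 of the level in CD8 T-like cells) and Rbm24 (1.93 [1.33, 2.58]) were the highest, and Rbm24 was −1.15 within the Penk-led cluster alone. Igha (−2.28 [−2.55, −2.02]) and Jchain (−2.20 [−2.91, −1.54]) were the lowest, then Penk (−1.76 [−1.97, −1.56]) and Bmyc (−1.74 [−2.13, −1.37]). Igha and Jchain are plasma cell transcripts, here at a level per cell that rounds to 0.0 of that in plasma-like cells. A single ad libitum cell held 224 of the 511 Igha UMIs, and 24 of the 79 Jchain UMIs were also in 1 cell. Without the top cells Igha was at −1.49 and Jchain at −1.80. Naive and central memory genes were lower (−0.62 [−0.88, −0.38]; 5 of 10 below and none above), with Ccr7 at −1.08 and Tcf7 at −0.89, as were follicular helper T genes (−0.43 [−0.65, −0.19]) and ribosomal proteins (−0.17 [−0.18, −0.16]; 78 of 80 below). Type 17 genes were higher (0.42 [0.16, 0.67]; 4 of 11 above), led by S100a4 (0.80), Tmem176b (0.78) and Ltb4r1 (0.62) and not by Il17a (0.08 [−0.41, 0.58]). Interferon genes were at 0.49 [0.27, 0.70] but at 0.00 with cells thinned to 1000 UMIs before summing, and the share of cells with at least 3 UMIs of the list at equal depth was lower in the FMD library (27.05% [21.13, 33.65] and 21.53% [16.92, 26.73]), so no direction is read for this list. Cytotoxic effector genes were at 0.17 [−0.02, 0.51] and checkpoint and exhaustion genes at −0.18 [−0.36, 0.01]. Part of these differences went with the clusters. In the Il10-led and the Penk-led cluster taken alone, Lag3 was at 1.10 and 0.78 [−0.08, 1.66], Gzmb at 1.03 and 1.53, Penk at −1.37 [−2.88, 0.13] and −0.81, and Bmyc at −1.45 and −0.97. Within a single cluster several lists turned: the type 17 median was −0.01 in the Il10-led cluster, and the regulatory T and follicular helper T medians were both 0.15 in the Penk-led cluster.

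CD8 T-like cells were compared for cytotoxic and naive programs. Naive and central memory genes were slightly higher in the FMD library (0.14 [0.08, 0.22]; 6 of 12 members above and 1 below), with Dapl1 at 1.05 and Ccr7 at 0.54, and Il7r at −0.47. Cytotoxic genes had a median of −0.04 [−0.13, 0.07] that moved both ways with the processing, from −0.25 at Leiden resolution 0.5 to 0.18 with cells thinned to 1000 UMIs before summing. Among single genes of this list, granzyme A gene Gzma was lower (−0.89 [−1.06, −0.73]) and the interferon gamma gene Ifng higher (0.49 [0.30, 0.69]). Checkpoint and exhaustion genes were lower (−0.31 [−0.46, −0.14]; 4 of 12 below and none above). The cluster led by Klra7 and Xcl1, where Cd8a was in 32.5% of cells, held the most ad libitum cells of this class (140 of 364) and 94 of its 285 FMD cells, so differences of the class also carry its weight; the naive cluster led by Dapl1 and Cd8b1 held the most FMD cells.

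Of 5168 genes, 6 were at least 2-fold higher and 8 lower in CD8 T-like cells. Igkc (3.30), Igha (3.11) and Jchain (2.72) were the highest through 1 or 2 FMD cells full of antibody transcripts, and Jchain was −0.67 without its top cells. Tsc22d1 was at 1.07 [0.62, 1.53]. The lowest were Iglc1 (−4.26 [−5.91, −3.00], free RNA), Slc15a2 (−1.66 [−2.39, −0.99]), Lgals3 (−1.40 [−1.84, −0.99]) and the cytokine gene Tnfsf11 (−1.25 [−1.90, −0.64]; 0.09 at Leiden resolution 0.5). Lgals3, at 0.017 of the level per cell in macrophage or dendritic-like cells, and Tnfsf11, at 0.076 of that in innate lymphoid-like cells, lie where this level by itself leaves free RNA open. The 89 and 30 Tnfsf11 UMIs lay in 28 and 11 cells, up to 12 and 7 in 1 cell, which argues against evenly spread free RNA. The 205 ad libitum Lgals3 UMIs lay in 55 cells, up to 26 in 1, but the 62 FMD ones in 44, up to 3 in 1. Regulatory T genes were at −0.35 [−0.49, −0.21] and follicular helper T genes at −0.23 [−0.42, −0.03]. Ribosomal proteins were at 0.04 [0.03, 0.05], and interferon genes at 0.14 [−0.04, 0.27], which was 0.88 with at most 10% mitochondrial UMIs, 0.86 at Leiden resolution 0.5 and 0.90 at Leiden resolution 2, where helper or naive T-like cells had 0.21, 0.03 and 0.26.

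In the unnamed cluster with B cell markers, 1 of 4074 genes was at least 2-fold higher and 11 were lower in the FMD library. The adaptor gene Tyrobp was the highest (1.44 [0.93, 1.97]), at 0.015 of the level per cell in macrophage or dendritic-like cells, so that free RNA is left open, then Gadd45a (0.90), Atp1b3 (0.80) and Cd55 (0.79). Slc15a2 was the lowest here too (−2.20 [−2.99, −1.49]), then the chemokine gene Ccl4 (−1.77; 69 of its 114 ad libitum UMIs in 1 cell), the heat shock gene Hspa1a (−1.41) and Hps4 (−1.28). Ccl4 (0.002 of the level in mast-like cells) and Hspa1a (0.078 of that in plasma-like cells) also lie where this level by itself leaves free RNA open. Their spread argues against free RNA taken up evenly by all cells. The 419 and 127 Hspa1a UMIs lay in 66 and 31 cells, with up to 39 and 31 in 1 cell. The 114 and 27 Ccl4 UMIs lay in 11 and 7 cells.

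The myeloid lists compared inflammatory with tissue repair programs. In macrophage or dendritic-like cells (79 and 139 cells), inflammatory genes were lower in the FMD library, with a median of −0.91 [−1.38, −0.80] and 14 of 17 members below 0 against 2 above. Tnf was at −2.0, the chemokine genes Cxcl1 and Cxcl10 at −2.80 and −2.67, and Il1b at −0.14. Immediate early and heat shock genes, which also mark handling, were lower in the same cells (−0.29 [−0.35, −0.24], 16 of 22 members below and 1 above). Whether handling took part in the inflammatory difference was not tested. Tissue repair and suppressive genes were higher (1.32 [0.84, 1.94], 9 of 13 above and 2 below), with the scavenger receptor gene Mrc1 at 2.71, Apoe at 2.34 and Arg1 at 1.32, and the cytokine gene Il10 at −3.42. That median was 0.23 without doublet removal. The list members C1qa, C1qb and C1qc were found in only 12 to 17 FMD cells and 1 to 2 ad libitum cells. The class mixes macrophage and dendritic markers. A change in which cells it holds therefore cannot be told apart from a changed program within cells. Lipid handling genes were at 0.27 [0.10, 0.48] and interferon genes at −0.53 [−0.69, −0.38] (−0.23 with cells thinned to 1000 UMIs before summing). In neutrophil-like cells (71 and 55 cells) the inflammatory list was lower too (−0.57 [−0.78, −0.31], 9 of 13 members below and 2 above). The granulocytic suppressor list was at 0.13 [−0.01, 0.26], with 5 of 18 members above 0 by their interval and 5 below. Il1b was at −0.76 and Ifitm1 at −1.41, and Lcn2 at 0.51 and Ngp at 3.42, the last with 534 of its 594 FMD UMIs in 1 cell.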

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

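The tests of broken plasma-like cells, of dilution by follicle B cells, of free RNA from macrophages, of heavy chain segments alone and of a sequence difference were chosen after the results they measure were seen.

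Plasma-like and IgA cells were fewer in the FMD library (2.76-fold and 3.99-fold, the latter with B-like calls that may be free RNA counted in). Plasma cells that broke open in the FMD suspension would leave their RNA in it, but Igha in B-like cells, where it lies at the free RNA level, had a log2 ratio of −1.75 [−1.87, −1.64]. More B cells from lymphoid follicles would raise the B-like share, but it was 58.25% and 55.95%, although the few germinal center B-like cells were 1.21% and 1.73%. Outside the B-like classes the plasma-like share was also lower (−1.57 [−2.14, −1.0]). That value argues against dilution by B cells alone. It cannot exclude dilution by T cells taken along with follicles, which would act there too. For a single expanded clone in the ad libitum pool, the most common pair of heavy and light chain variable segments held 3 of 52 cells with a pair (5.8% [1.2, 15.9]). Pairs cannot exclude a clone, because 41 of 46 ad libitum cells led by a lambda segment had more kappa constant UMIs. By heavy chain segments alone, the most common held 6 of 54 cells (11.1% [4.2, 22.6]). This speaks against 1 clone holding most of those cells, if their segments were called rightly, which was not tested. The other plasma-like cells, of 93 in all, had no heavy chain segment call. Fewer plasma cells in FMD tumors thus stays a hypothesis, and differences between the mice, in how much follicle-free mucosa was taken, or in how intact plasma cells survived the digestion of each pool stay open, since 1 pool per diet leaves them untested.

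Type I interferon genes were higher in B-like and helper or naive T-like cells of the FMD library (0.53 and 0.68). Free RNA of macrophage or dendritic-like cells would bring their other abundant transcripts along. To give the differences, a median of 7.41% [4.90, 9.49] of the RNA in B-like and 27.06% [20.57, 30.83] in helper or naive T-like cells of the FMD library would have to be of the kind in the kept macrophage class, while 10 abundant macrophage markers allow a median of at most 0.72% and 1.37%, and 9 of the 10 lie below those intervals in each class, all but Apoe in B-like and Ccr2 in helper or naive T-like cells. This argues against such RNA as the source for the list as a whole. It does not for Ifit1 (0.41%) and Ifitm3 (0.20%) in B-like cells, and the B-like median was 0.17 without genes at the free RNA level, against 0.72 in helper or naive T-like cells. An earlier test on the ratios of 5 macrophage markers gave 0.05 [−0.53, 0.37] and decided nothing. Deeper FMD cells are argued against by the B-like median at equal depth, 0.47 [0.21, 0.74]; in helper or naive T-like cells the median was 0.54 at equal depth, but 0.03 at Leiden resolution 0.5. More B-like cells in an interferon-high state cannot be told apart from a shift of all B-like cells: the median was 0.01 [−0.08, 0.13] over 17 members without the cluster led by interferon genes, but that cluster is defined by the genes measured. An infection or another cause in some of the pooled mice stays open and was not tested.

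Slc15a2 was lower in the FMD library in all 7 classes with at least 50 UMIs, from −2.21 in B-like to −1.16 in macrophage or dendritic-like cells. Different shares of B-like clusters are argued against by the clusters taken singly, whose highest ratio was −1.06. A change over the chromosomal region is argued against by the 7 genes within 500000 bases, whose median was 0.06 [−0.04, 0.18]. A sequence difference between the mice of both pools cannot be told apart from an effect of diet: no class lay near 0 (highest −1.16 [−1.80, −0.53]), and although the interval of B-like cells ([−2.42, −1.99]) does not overlap that one, a variant can act more strongly in 1 cell type and the pools can contribute unequally to a class. Regulation of this transporter gene by the diet remains a hypothesis.

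Type 17 genes had a median of 0.42 in regulatory T-like cells and −0.32 in helper or naive T-like cells, opposite directions whose difference was not tested. The regulatory T-like median was −0.01 in the Il10-led cluster alone, which held most FMD cells of the class. In the Penk-led cluster alone it stayed within the counting interval of the class. Ribosomal protein genes were at 0.04 in helper or naive T-like and −0.17 in regulatory T-like cells, a difference that was not tested either. Naive and central memory T genes were at 0.14 in CD8 T-like and −0.62 in regulatory T-like cells, also with no test of the difference. Barcodes removed by the filters, which entered only the alternatives over all barcodes or with looser filters, held 39067 hemoglobin UMIs in the ad libitum library (1220 barcodes) and 1356 in the FMD library (1255 barcodes), while kept cells held 80 and 3711. Hemoglobin made up most UMIs in only 6 and 1 of the removed barcodes, and 0 and 2 kept cells held over 100 hemoglobin UMIs. Few barcodes may therefore set these totals.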

How the results depend on the processing

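Chosen after the data were seen were the alternatives with a Scrublet score limit, the unnamed cluster counted as B-like, the class minimum of 30 cells, the top cells left out, the interferon cluster left out, regulatory T-like clusters alone, the first naming rule and the other marker score. No paired analysis was possible because the libraries share only replicate number 1, and with 1 library per diet no library could be left out and no other split of the samples exists. The log2 ratios of shares kept their direction under all 12 alternatives for B-like (−0.08 to −0.04), plasma-like (−1.49 to −1.0), T and NK-like (0.12 to 0.17) and myeloid-like cells (0.06 to 0.52), and so did IgA cells among B and plasma-like cells under 16 (−2.06 to −1.42), IgA cells among plasma-like cells (−0.74 to −0.29) and Igha CPM under 6 (−1.46 to −1.37). Of 58 other class shares and named genes, 803 alternative values gave 710 within the counting interval, 86 outside it with the same sign, 1 outside it with the other sign and 6 reversed. The exception was the mast-like share, −0.16 with classes from marker scores per cell against 1.08, whose interval had reached 0. That setting also gave the lowest share ratios of innate lymphoid-like (0.44), macrophage or dendritic-like (0.08) and regulatory T-like cells (0.07). The class minimum of 30 cells only adds classes, whose values stand among the other observations, and a list with fewer than 5 members left gave no value. For values below, the cause was not tested, except that higher minimum counts, thinning and genes left out leave fewer genes to count.

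With at most 10% mitochondrial UMIs, Igha CPM was −1.39; in helper or naive T-like cells interferon was 0.21, ribosomal 0.02, checkpoint −0.23, regulatory T −0.35 and type 17 −0.16; in regulatory T-like cells 19 genes were 2-fold apart, regulatory T was −0.46, naive T −0.27 and ribosomal −0.09; in CD8 T-like cells 23 genes were 2-fold apart, cytotoxic was −0.19, checkpoint −0.09, regulatory T −0.13, interferon 0.88 and ribosomal 0.02. With at least 500 genes, IgA among B-like cells was −1.38, helper regulatory T −0.35, regulatory T-like naive T −0.24 and ribosomal −0.10, CD8 cytotoxic −0.15 and the CD8 gene count 25. With no doublet removal, IgA among B-like cells was −1.96, Igha CPM −1.46, helper glycolysis −0.04, interferon 0.91 and ribosomal 0.02, regulatory T-like ribosomal −0.14 and macrophage tissue repair 0.23. At Leiden resolution 0.5 the CD8 share was 0.03, reversed, as were helper follicular helper T (0.02) and Mx1 (−0.20) and CD8 Tnfsf11 (0.09). There, helper FOXO was 0.02, interferon 0.03, MHC class I −0.15, immediate early 0.01, ribosomal 0.01, regulatory T −0.36, type 17 −0.17 and naive T −0.07, regulatory T-like regulatory T −0.48, naive T −0.22 and ribosomal −0.10, and CD8 cytotoxic −0.25, regulatory T −0.09, naive T 0.07, interferon 0.86 and ribosomal 0.01, with 26 CD8 genes. At resolution 2, helper interferon was 0.26, CD8 cytotoxic −0.16, naive T 0.24, interferon 0.90 and ribosomal 0.05. With receptor and ribosomal genes kept for clustering, helper naive T was 0.16 and CD8 Jchain −0.67, reversed.

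With a Scrublet score limit of 0.2, Igha CPM was −1.44, B-like ribosomal −0.02, regulatory T-like ribosomal −0.19 and the gene count of the unnamed B cell cluster 7. With that cluster counted as B-like, IgA among B-like cells was −1.95, B-like unfolded protein −0.05, germinal center −0.20 and NF-kB −0.06. With classes from marker scores per cell, the myeloid share was 0.06, IgA among plasma-like cells −0.74 and IgA among B-like cells 1.72, reversed. With all UMIs as the denominator Igha CPM was −1.37 and B-like ribosomal −0.02, and over all barcodes Igha CPM was −1.46. With TMM factors, ribosomal was −0.02 in B-like, 0.05 in helper, −0.20 in regulatory T-like and 0.05 in CD8 T-like cells.

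With cells thinned to 1000 UMIs before summing, the gene counts were 8 in B-like, 8 in helper, 7 in regulatory T-like, 3 in CD8 T-like cells and 4 in the unnamed B cell cluster. B-like fatty acid oxidation was then 0.05, glycolysis 0.11, FOXO −0.12, glucocorticoid −0.22, immediate early −0.27, ribosomal −0.02, switch recombination −0.24 and fibroblast and erythroid 5.46. Plasma-like secretory was −0.35 and unfolded protein −0.31, reversed. Helper unfolded protein was 0.19, sterol synthesis 0.05, ribosomal 0.02, checkpoint −0.41, regulatory T −0.41 and type 17 −0.82, regulatory T-like checkpoint 0.15, interferon 0.00 and ribosomal −0.13, and CD8 cytotoxic 0.18, regulatory T −0.51, naive T 0.23 and interferon 0.31. Macrophage tissue repair was 1.99, lipid 0.51 and interferon −0.23, and neutrophil granulocytic suppressor −0.03.

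With minimums of 50 and 10 UMIs the gene counts were 44 in B-like, 79 in helper, 95 in regulatory T-like, 38 in CD8 T-like cells and 40 in the unnamed B cell cluster, and with minimums of 400 and 50 UMIs they were 6, 10, 7, 4 and 4. Without genes at the free RNA level they were 6 in B-like, 24 in helper, 5 in CD8 T-like cells and 5 in the unnamed cluster, with B-like interferon at 0.17 and MHC class I at −0.09 and macrophage inflammatory at −1.90. Without the top cell of each gene, B-like fibroblast and erythroid was 5.62, plasma-like unfolded protein 0.00, regulatory T-like ribosomal −0.16, CD8 Jchain −0.67, reversed, and macrophage interferon −0.34. Without the interferon cluster, B-like interferon was 0.01 and MHC class I −0.11. In the Il10-led regulatory T-like cluster alone, the gene count was 19, cytotoxic 0.73, checkpoint 0.11, regulatory T −0.10, type 17 −0.01, reversed, naive T −0.34, follicular helper T −0.05 and ribosomal −0.12. In the Penk-led cluster alone the count was 16, cytotoxic 0.90, checkpoint 0.13, ribosomal −0.10, and regulatory T (0.15), follicular helper T (0.15) and Rbm24 (−1.15) were reversed.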

Other observations

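The values here are from classes with fewer than 100 cells in a library and were looked at after the other results were seen. In macrophage or dendritic-like cells (118 genes at least 2-fold apart, 41 of them higher in FMD), the complement genes of resident macrophages were higher in the FMD library. C1qa had 1 and 146 UMIs (6.44 [3.94, 11.76]), C1qc 2 and 143 (5.41 [3.53, 8.47]) and C1qb 13 and 322 (3.88 [3.09, 4.81]), in 12 to 17 FMD cells of 139. The transcription factor gene Maf was also higher (3.58 [2.31, 5.23]). On the other side, Il23a, a subunit of the cytokine that sustains type 17 cells, had 66 and 3 UMIs (−5.21 [−7.52, −3.60]), Nos2, which makes nitric oxide, had 34 and 0, and the chemokine gene Cxcl9 was at −2.36 [−2.63, −2.09]. Krt19, Krt15, Wfdc2 and Ltf, epithelial or secretory genes, came from 1 ad libitum cell. In innate lymphoid-like cells (29 genes), Ipmk (1.82 [1.19, 2.52]) and the nuclear receptor gene Nr4a2 (1.32 [0.82, 1.85]) were higher and Ncoa7 (−1.57 [−2.04, −1.09]) and Klrd1 (−1.62 [−2.18, −1.06]) lower in the FMD library, while the type 2 regulator gene Gata3 was at 0.53. Gamma delta T-like cells (11 genes) had lower Cd72 (−1.68 [−2.47, −0.96]) and Cxcr4 (−1.40 [−1.80, −1.01]). Neutrophil-like cells (31 genes) had lower Cxcl10 (−4.08 [−5.10, −3.22]) and Saa3 (−4.51 [−6.41, −3.13]) and higher Hilpda (1.72 [1.40, 2.05]), and the granule genes Camp and Ltf were high through 1 FMD cell each.

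Plasma-like cells (44 genes) differed most in antibody genes. Ighg1 had 15992 UMIs in 12 ad libitum cells and none in the FMD library, Ighg3 had 131 and 18907 UMIs, the latter in 7 cells, and Ighm was higher in the FMD library (5.39 [5.25, 5.54]). The lambda light chain genes Iglc1 (−4.50 [−4.59, −4.40]) and Iglc2 (−2.78 [−2.85, −2.72]) were lower, and cells with more lambda than kappa constant UMIs were 7 of 93 (7.5% [3.1, 14.9]) against 0 of 32, with an upper bound of 10.9%, so that their share was not detectably different. The variable segments do not serve for this call, because lambda segments, such as Iglv1 of the most common FMD pair (2 cells), led the light chain segments of 15 FMD cells, all of them with more kappa constant UMIs, and of 46 ad libitum cells, 41 of them with more kappa constant UMIs. With so few plasma-like cells, single cells set these ratios: Iglc1 was at −3.68 without its top cells. The 52 ad libitum cells with a variable segment pair had 41 distinct pairs, and the 14 FMD cells had 13; by heavy chain segments alone, 54 cells had 33 and 15 had 14. Germinal center B-like cells (64 genes) had higher Ighg1 in the FMD library (6.03 [4.46, 8.31], in 8 cells), and their lower Ighg2b (−2.87 [−2.97, −2.77]) was −0.20 without its top cells. Epithelial markers, which a CD45 sort should exclude, had 1372 UMIs in ad libitum and 386 in FMD kept cells, but 378 of the former were Krt19 in 1 cell, and 3 cells in each library had at least 3 of the 11 markers.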
